A study of Lactiplantibacillus plantarum with 10 samples.

How the data were processed

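Each culture was quenched in a buffered methanol solution, and its total RNA was extracted, reverse transcribed and labelled with Cy3 or Cy5, per the labels' protocols. A pair of labelled samples was hybridised to each array. Spots were quantified with ImaGene, per the file headers, and each deposited file gives linear intensity values per spot for both channels, with local background, flag codes and a mark for empty spots. These intensity values were deposited without background correction or normalization. The authors also deposited log2 ratios in a table with a column per array, and the submitters' processing notes name limma, with no version or settings. Set against the scanner values, that table was log2 of Cy3 over Cy5, with the correlation to the log2(Cy5/Cy3) values computed here between -0.995 and -0.793. Its column medians were 0.0057, 0.015, -0.0050, 0.021, -0.0049, -0.0050, 0.022, 0.034, -0.0089 and -0.013 for arrays 1 to 10. Scale, direction and centring near 0 were found by that comparison, and the normalization method behind the table is not given in the sources used here. The table served only as an alternative.

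The arrays were numbered in the order in which they are listed. Arrays 1 to 10 carried, Cy3 first, reactors 1 and 2, 2 and 5, 5 and 4, 4 and 1, 2 and 3, 3 and 6, 6 and 1, 6 and 5, 5 and 4, and 5 and 6. Array 9 repeated array 3 with new labelling, and array 10 was the dye swap of array 8.

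Each array held 10807 spots, of which 10221 belonged to 9170 probes for 3092 locus tags. The other 586 spots, controls among them, were left out after background correction. Background was corrected with normexp (offset 50) on mean signal and median local background, and log2(Cy5/Cy3) was normalised within arrays by loess with those spots at weight 0 (limma 3.58.1, R 4.3.3, statmod 1.5.0, and data.table in version 1.17.8). Spots with flag codes 1 and 6, which lay in contiguous patches as manual masks do, were left out. This was decided after the files were seen and before any test, as the meaning of the codes is not given in the sources used here. Saturated spots were kept. A probe was used if it was above background (not marked empty, a mark that equalled a signal under 2 background SDs) in at least 0.5 of the channels with respiring RNA or 0.5 of those with aerobic RNA. This left 7899 probes of 2909 genes on the 7 arrays without reactor 4, and 8351 probes of 3006 genes on all 10. Spots of a probe and then probes of a gene were averaged, with a median of 3 probes per gene.

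The culture was the replicate. In a first step, lmFit estimated a log2 level per culture and gene, with a gene-specific dye effect. In a second step, lmFit and eBayes compared those levels, 3 respiring cultures against reactors 5 and 6, on the 7 arrays without reactor 4, as the series description leaves that reactor out. For reactor 4, all 10 arrays were used with 3 groups, and the lone culture was assumed to vary like the others. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The median residual SD was 0.0852 in the first step and 0.143 between cultures in the second (log2). The methods were tested on simulated data of 2819 genes with 200 changed. For respiring against aerobic, 44.9% of genes changed by 0.5 on the log2 scale were recovered, 96.6% at 1 and 99.9% at 2, and 5.39% of calls were false. With array noise alone and no spread between cultures, 8.80% of unchanged genes had p under 0.05. For reactor 4, recovery was 11.7%, 86.2% and 99.6%, and 4.74% of calls were false. Both simulations gave the cultures of a gene the same spread in every condition. In the data, reactors 5 and 6 lay further apart (SD of the log2 difference over genes 0.421) than the respiring pairs (0.168 to 0.238). The simulations could not show how this affects the share of false calls.

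Of 23 gene lists fixed before the data were examined, 15 were written as gene symbols only. They could not be applied, because the files give locus tags without symbols, and the gene table at hand, of another strain, matched 0 of the tags. The 8 lists also written as tags were used by those tags alone, without their gene symbols: respiratory chain, F1F0 ATPase, oxidative stress and redox, pyruvate dissipation, purine synthesis, pyrimidine synthesis, fatty acid synthesis, and heat shock and protease. Their tags come from general knowledge of the strain's annotation and could not be checked against the files. The 6 lists with at least 3 members were tested with camera (preset correlation 0.01, and with an estimated one) and with fry, adjusted over the 6 lists. The design, the tests, the lists and the alternatives were otherwise fixed before the data were examined. The rule for named genes took the 10 largest increases and 10 largest decreases past the threshold with fully separate cultures. It added, from each list, the 2 largest increases and decreases past the threshold (or the 2 smallest p), the 4 tags set down for the cytochrome bd oxidase and its assembly, and for reactor 4 the 6 largest increases past the threshold and, as fewer than 3 genes fell, the 6 decreases of smallest p. For reactor 4 all 18 genes past the threshold were followed through the alternatives, 24 genes in all. From these, few tags are printed, since the files do not name them.

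Alternatives changed the background correction, normalization, filter, averaging of probes, saturated and masked spots, the test, the treatment of dye, slide and reactor 4, and left out each culture and array in turn. Python 3.11.15 and matplotlib 3.10.9 drew the figures.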

Results

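RNA levels of the lactic acid bacterium Lactiplantibacillus plantarum, strain WCFS1, were measured on 10 two-colour oligonucleotide arrays on 5 slides. Batch cultures in MRS broth, without pH control, were grown in 6 reactors. Reactors 1, 2 and 3 received heme and vitamin K2, the cofactors that let this bacterium assemble an aerobic electron transport chain, and are called respiring. Reactors 4, 5 and 6 received neither and are called aerobic. The labels describe the cultures as grown and harvested independently, so p-values here measure the spread between cultures. Each array compared 2 cultures, and together the arrays formed a loop. The share of gene probes above background ranged over channels from 48.2% (reactor 6 on array 6) to 99.6% (reactor 5 on array 3), against 0.886% of negative control spots. The number of cultures limits the precision of every value below. Genes are given by locus tag, because the files pair the tags with no gene names, and no coordinates are given.

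The first comparison asked which genes differ between respiring and aerobic cultures, with 3 respiring cultures against reactors 5 and 6. Respiring cultures had far more RNA of the purine synthesis list and far less of the fatty acid synthesis, pyrimidine synthesis and F1F0 ATPase lists. The 11 purine genes rose by a median of 18.6-fold. The 13 fatty acid genes fell by a median of 11.8-fold, the 8 pyrimidine genes by 8.20-fold and the 8 F1F0 ATPase genes by 3.09-fold. Large decreases were not limited to the lists. Outside them, 31 neighbouring measured genes, from lp_1025 to lp_1062, fell by a median of 8.77-fold, a run picked after its values were seen. Of the 10 genes with the largest increase, 9 belonged to the purine list, and of the 10 with the largest decrease, 9 belonged to the fatty acid list and 1 to the pyrimidine list.

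Across the genome, 501 genes were higher and 591 were lower in respiring cultures among the 2909 tested (limma, Benjamini-Hochberg adjusted p under 0.05), which is 37.5% of them. Most changes were modest. The median change was 1.64-fold among the higher genes and 1.70-fold among the lower ones, and 128 higher and 184 lower genes changed at least 2-fold. Leaving out reactor 1 gave 276 higher and 332 lower genes, and leaving out reactor 3 gave 285 and 350.

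The purine list, 11 neighbouring tags for the synthesis of purine nucleotides, rose in 11 of 11 members, over all genes tested and adjusted over the list alone. Its median level across members, relative to each gene's mean over the 5 cultures, was 1.69 ± 0.37 on the log2 scale in respiring cultures (SD, n = 3) and -2.51 ± 0.26 in aerobic cultures (SD, n = 2). The members rose by 3.79 to 4.49 on the log2 scale. The largest increases were those of lp_2720 (4.49 ± 0.18, SE, 22.4-fold, adjusted p = 1.3e-04) and lp_2726 (4.40 ± 0.26, SE, 21.1-fold). As a group the list ranked above the other genes by camera with a preset correlation (adjusted p = 4.0e-11 over 6 lists), a call that was lost with an estimated one (adjusted p = 0.238 with an estimated correlation). When reactor 4 was counted among the aerobic cultures, only 1 of the 11 members passed the threshold and the median difference was 2.81 (log2), still higher in respiring cultures.

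The fatty acid list, 13 neighbouring tags for building and elongating fatty acid chains, fell in 13 of 13 members, and the same 13 of 13 passed adjusted over the list alone. Its median level was -1.42 ± 0.39 in respiring cultures (SD, n = 3) and 2.21 ± 0.43 in aerobic cultures (SD, n = 2). Differences ran from -3.91 to -3.29, with the largest at lp_1678 (-3.91 ± 0.32, SE, 15.0-fold lower, adjusted p = 5.1e-04) and lp_1676 (-3.84 ± 0.32, SE). Camera gave adjusted p = 1.3e-10 with the preset correlation, and adjusted p = 0.238 with an estimated correlation.

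All 8 members of the pyrimidine list, the tags for making pyrimidine nucleotides, fell, over all genes and adjusted over the list alone. The median difference was -3.03 and the members ranged from -3.54 (lp_2700, SE 0.39) to -2.28. That of lp_2700 was -4.22 without reactor 5 and -2.86 without reactor 6. Camera gave adjusted p = 2.0e-06 with the preset correlation and adjusted p = 0.238 with an estimated correlation. The F1F0 ATPase list, the 8 tags for the proton-translocating ATPase, also fell in 8 of 8 members, over all genes and adjusted over the list alone. Its median difference was -1.63, with lp_2366 at -1.74 ± 0.25 (SE) and lp_2369 at -1.73 ± 0.20 (SE). Without reactor 3 that median was -1.48, and 7 of the 8 members passed over all genes. The size of the decrease depended on the processing. The median was -1.18 with median centring and -1.38 without background correction, with 8 of 8 members past the threshold in both. The camera values were adjusted p = 2.6e-05 with the preset correlation and adjusted p = 0.238 with an estimated correlation.

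**Figure D1:**
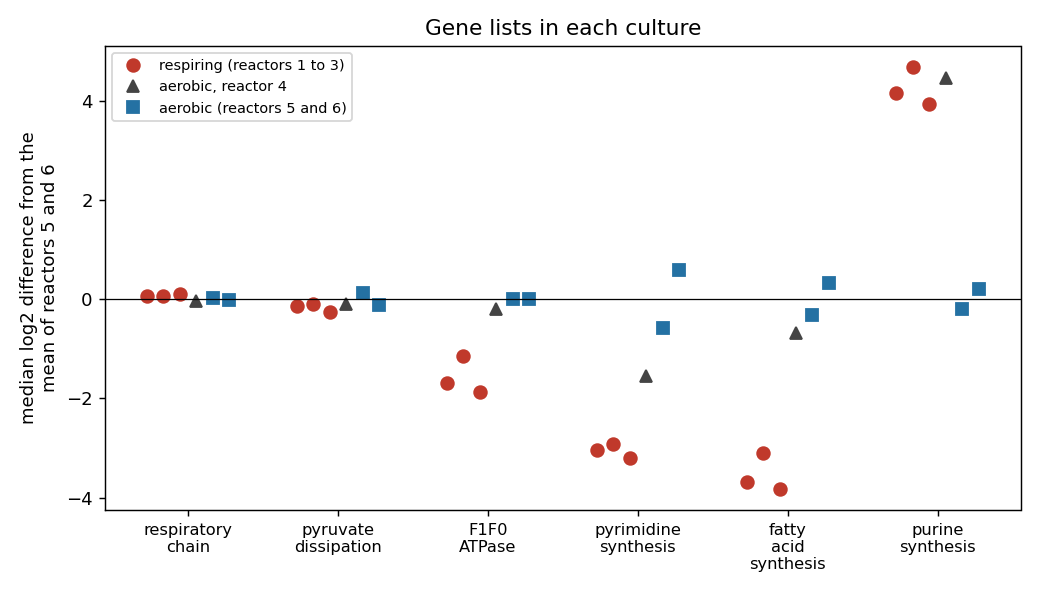
Median over the members of each gene list (y axis, log2 difference from the mean of reactors 5 and 6) for each of the 6 cultures (1 point per culture, no error bars). For the purine list, reactor 4 (triangle, 4.46) sits among the 3 respiring cultures (3.93 to 4.68), and for the fatty acid list (-0.69) it sits near the other aerobic cultures.

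These 4 lists had the same direction on each of the 3 arrays that held both conditions without reactor 4, each on its own slide. The arrays are part of the main fit and are not independent of each other. Array 2 held reactor 5, and arrays 6 and 7 both held reactor 6. The purine median (respiring minus aerobic, log2) was 4.70, 3.75 and 3.98 on arrays 2, 6 and 7. The fatty acid median was -2.78, -4.23 and -4.13 on those arrays, and the pyrimidine median was -2.39, -3.69 and -3.39. The F1F0 ATPase median was -1.17, -1.95 and -1.85. With the slide as a random block over arrays, 527 genes were higher and 594 lower.

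Genes of the respiratory chain list showed smaller differences. Of its 8 members, 2 rose, none fell and 6 did not pass, with the same counts adjusted over the list alone and a median difference of 0.09 (camera adjusted p = 0.707). The counts moved with the analysis: 3 rose and 1 fell with median centring, and 2 rose and 2 fell with the deposited table or with an intensity trend. The 2 that rose were among the 4 tags set down for the cytochrome bd oxidase, the terminal oxidase that uses heme, and for its assembly. They were lp_1125 (0.90 ± 0.18, SE, 1.86-fold, adjusted p = 0.0094) and lp_1128 (0.44 ± 0.10, SE, adjusted p = 0.016). The other 2 of these 4 tags had differences of 0.48 ± 0.24 (SE) at lp_1126 and 0.32 ± 0.13 (SE) at lp_1129, with adjusted p = 0.159 and 0.0935. The remaining 4 members, lp_1497 to lp_1500, differed by -0.23, -0.40, -0.14 and -0.24, none past the threshold. The list median near 0 thus lay between tags of opposite sign. Those 4 members were nearer to background. Their best-detected probes were above it in 0.571 to 0.857 of the channels with respiring RNA, against 1 for the cytochrome bd tags. The call of lp_1128 was lost when any one of the respiring cultures was left out, with differences still of 0.42 to 0.47, and without background correction its difference was 0.22, past the threshold. The differences of lp_1126 and lp_1129 were 0.90 and 0.43 without reactor 5, and 0.05 and 0.20 without reactor 6. The former passed with the median over probes (0.89) and with median centring (0.71), and the probes of each did not all have the same sign.

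The pyruvate dissipation list, which covers enzymes that turn pyruvate into lactate, acetate or acetyl-CoA, moved in both directions. Of 11 members, 1 rose, 3 fell and 7 did not pass, and adjusted over the list alone 3 rose and 4 fell. The balance turned with the analysis: 4 rose and 1 fell with median centring, 2 and 0 without background correction, and 1 and 0 without reactor 1 or 3. The member that rose was lp_0537 (1.09 ± 0.23, SE, 2.13-fold, adjusted p = 0.012), and those with the largest decreases were lp_3589 (-1.12 ± 0.29, SE, adjusted p = 0.027) and lp_2153 (-0.84 ± 0.24, SE, adjusted p = 0.034). The difference of lp_0537 was 0.70 without reactor 6 and 1.49 without reactor 5. All 3 calls were lost when reactor 3 was left out, with differences of 1.06, -1.13 and -0.65. The 2 decreases were also lost without reactor 1 (-1.12 and -0.83) and without background correction (-0.73 and -0.57). That of lp_3589 was lost too without reactor 2 and with arrays as replicates, and was -0.58 without reactor 5 and -1.66 without reactor 6. That of lp_2153 was lost too with median centring (-0.67) and with reactor 4 included (-0.57), and was -0.68 without reactor 6. As a group the list did not stand apart (median difference -0.19, camera adjusted p = 0.770). The single tag of the oxidative stress list, lp_3578, differed by 0.08 ± 0.15 (SE, adjusted p = 0.692), and the 2 heat shock tags, lp_0727 and lp_0728, each by -0.26 (SE 0.18 and 0.22, adjusted p = 0.298 and 0.375). With median centring lp_3578 passed at 0.74. The differences of the heat shock tags were -0.51 and -0.59 without reactor 6, and -0.01 and 0.06 without reactor 5. With median centring they were 0.36 and 0.32, not past the threshold.

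Outside the lists, the largest increase was that of lp_1289, which was 20.4-fold higher in respiring cultures (4.35 ± 0.14, SE, adjusted p = 8.8e-05). Its difference was 2.54 without background correction, 3.10 with reactor 4 included and 5.10 with the deposited table, each past the threshold.

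**Figure D2:**
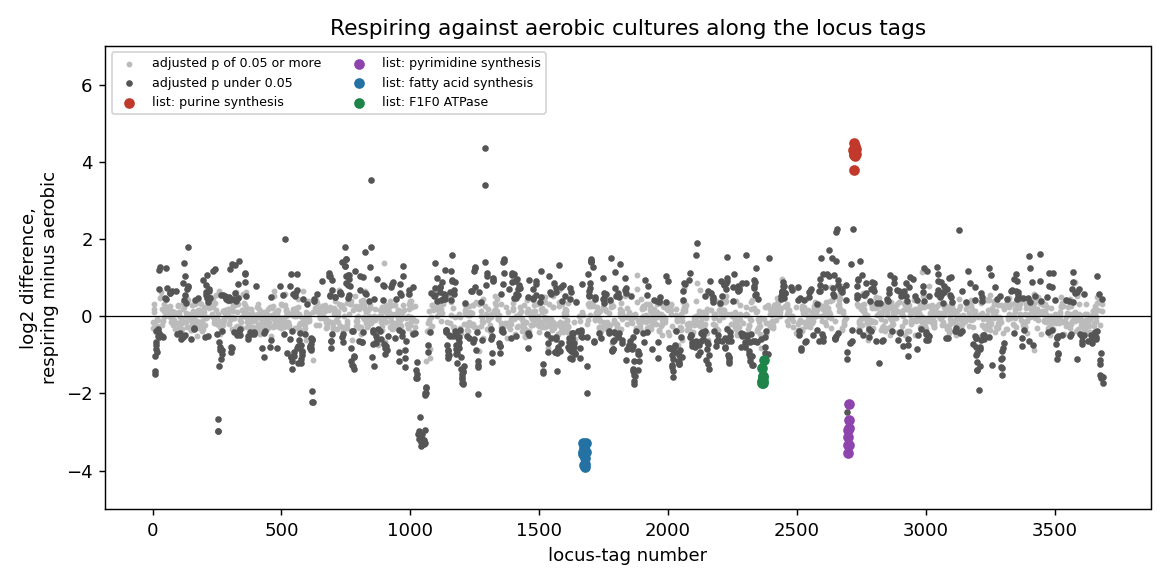
Log2 difference between respiring and aerobic cultures (y axis) for 2859 genes against the number in their locus tag (x axis). Each point is a gene, dark where the adjusted p is under 0.05 and coloured for 4 lists. The purine genes lie between 3.79 and 4.49, and the fatty acid, pyrimidine and F1F0 ATPase genes each form a block below 0.

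The second comparison asked how reactor 4, which the series description leaves out because of a probable quenching mistake, differs from the other aerobic cultures. The median of the purine list in reactor 4, 4.46 (log2) above the mean of reactors 5 and 6, lay within the range of the respiring cultures (3.93 to 4.68), while the fatty acid and F1F0 ATPase lists lay nearer to reactors 5 and 6. On array 4, which set reactor 1 against reactor 4 directly, the respiring minus aerobic median was -0.11 for the purine list and -3.03 for the fatty acid list. Of 3006 genes, 18 were higher in reactor 4 and 0 were lower (limma, adjusted p under 0.05), and 11 of the 18 were the whole purine list. The purine list was higher in 11 of 11 members, also adjusted over the list alone, with a median of 22.0-fold (camera adjusted p = 2.1e-28, and adjusted p = 0.180 with an estimated correlation). The largest differences were at lp_2726 (4.65 ± 0.36, SE, adjusted p = 0.0035) and lp_2728 (4.59 ± 0.28, SE, adjusted p = 0.0024). Outside the list, lp_1289 was 11.6-fold higher (3.54 ± 0.17, SE, adjusted p = 0.0016).

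The pyrimidine list had a median of -1.56 in reactor 4, intermediate between the 2 conditions. None of its 8 members passed over all genes and 8 were lower adjusted over the list alone (camera adjusted p = 5.7e-08, and adjusted p = 0.367 with an estimated correlation). The fatty acid list had a median of -0.69, with 0 of 13 members past either threshold (camera adjusted p = 3.6e-05, and adjusted p = 0.501 with an estimated correlation). The F1F0 ATPase list had a median of -0.20, with 0 of 8 members past the threshold over all genes and 1 lower adjusted over the list alone (camera adjusted p = 0.0975). No member of the respiratory chain list (median -0.04, camera adjusted p = 0.965) or the pyruvate list (median -0.10, camera adjusted p = 0.811) passed, over all genes or adjusted over the list alone. The oxidative stress tag lp_3578 differed by 0.12 ± 0.23 (SE), and the heat shock tags had a median of 0.60, neither past the threshold.

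Without adjustment, 345 genes had p under 0.05 in this comparison, 195 of them lower in reactor 4, where 150.3 in all would come from chance. Reactor 4 is a lone culture assumed to vary like the others. The count moved with the analysis: it became 275 higher and 191 lower without reactor 5, 34 and 43 without reactor 6, and 6 and 0 without background correction. Without background correction 3 of the 11 purine members passed, with differences of 2.54 to 4.05 over the list, and lp_1289 passed at 1.99.

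Set against the 3 respiring cultures, in a comparison added after the data were examined, reactor 4 had 87 genes higher and 42 lower. The fatty acid list was higher in 13 of 13 members, also adjusted over the list alone (median 2.87, 7.33-fold, camera adjusted p = 3.8e-16, and adjusted p = 0.339 with an estimated correlation). The F1F0 ATPase list was higher in 4 of 8, and in 8 of 8 adjusted over the list alone (median 1.40, camera adjusted p = 1.3e-06, and adjusted p = 0.339 with an estimated correlation). The pyrimidine list was higher in 2 of 8, and in 6 of 8 adjusted over the list alone (median 1.78, camera adjusted p = 1.2e-05, and adjusted p = 0.368 with an estimated correlation). The 2 heat shock tags (median 0.77) were higher only when adjusted over their list alone. No purine gene passed either way, and that list's median difference was 0.21 (camera adjusted p = 0.955).

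The third comparison set the spread between cultures of one condition beside the difference between conditions. Over genes, the SD of the log2 difference was 0.168 to 0.238 between respiring cultures and 0.421 between reactors 5 and 6. It was 0.732 to 0.835 between a respiring culture and reactor 5 or 6. Reactors 5 and 6 differed at least 2-fold in 92 genes, and the respiring pairs in 0 to 4. Reactor 4 lay 0.425 from reactor 5, 0.518 from reactor 6 and 0.459 to 0.549 from the respiring cultures. The dye-swapped arrays of reactors 5 and 6 correlated at 0.923 across genes. The 2 labellings of reactors 5 and 4, in the same dye orientation, correlated at 0.955. Genes are not independent replicates in either value.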

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

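All tests of explanations in this part were chosen after the result was seen, except the ratio of dimmer to brighter genes and the agreement of probes.

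Array 6 had 1547 masked spots, far from the other 3 arrays with both conditions. Array 8 had 480, far from the other 3 arrays with 2 aerobic cultures. On array 2 the median of the respiratory chain list was 0.013 (log2, respiring minus aerobic), apart from the other 3 arrays with both conditions, where it was 0.12 to 0.14. For independent, normally distributed values such a gap would arise by chance in about 1 of 20 groups, and 16 were examined. Counts of masked spots need not be such values, and the groups share arrays, so this rate may not hold.

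Several probes without a locus tag gave signal outside the comparisons. Spot channels above background made up 97.2% for the 16 spots named mtf_9, 85.3% for the 16 spots of its reverse, 93.8% for the 4 mtf_gen spots and 100% for the 3 SRP spots. They made up 11.7% for the 3 spots marked antisense to a locus tag, against 0.886% for the 79 negative control spots.

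Reactor 4 had the purine genes of a respiring culture beside fatty acid genes close to the aerobic ones. A failed labelling is argued against by the 0.955 correlation of the log ratios from 2 labellings. Both had the same dye orientation, so a gene-specific dye effect common to them would raise that correlation. A respiring sample under a wrong label is argued against by the fatty acid list, which lay 2.87 (log2) above the respiring cultures. A mixture of RNA at the mean respiring and mean aerobic levels would imply 1 share for all lists. The implied share was 1.13 from the purine list (0.547 to 1.28 over genes) and 0.445 from the fatty acid list (0.297 to 0.461). The difference of 0.683 argues against a mixture of these means. The pyrimidine list gave 0.772 (0.474 to 0.902), which overlaps the purine range and not the fatty acid range, and the F1F0 ATPase list gave 0.199 (-0.110 to 0.747), which overlaps all 3. These ranges are over genes and leave out the spread between cultures. A mixture of RNA from single cultures, rather than of the condition means, was not tested on the lists and stays open for them. No mixture lies above its highest part. Yet lp_2710 was at 1.37 in reactor 4, where the highest other culture was at 0.37 (log2, relative to the mean over cultures). For lp_3271 these levels were 0.97 and -0.02. This argues against such a mixture as the whole cause for these genes, which were picked from the 18 past the threshold. The quenching mistake named in the series description and a true difference of the reactor 4 culture were not tested and stay open.

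Reactors 5 and 6 lay further apart (SD 0.421) than any respiring pair (0.168 to 0.238). Hybridisation noise is argued against by the 0.923 correlation of the dye-swapped arrays. The SD of the difference over the dimmer genes was 0.641 of that over the brighter ones, but the respiring pairs gave 0.585 to 0.796, so this ratio does not set reactors 5 and 6 apart. Noise of dim spots as the whole cause is argued against by the brighter genes alone, where the SD was 0.505 against 0.194 to 0.291 for the respiring pairs. One of them lying closer to the respiring state, as the whole cause of their gap, is argued against by a correlation of 0.0672 across genes between their difference and the difference of conditions. Reactor 5 did lie slightly closer than reactor 6 to each respiring culture (SD 0.732 to 0.794 against 0.754 to 0.835). From the mean of both, it lay toward them in the pyrimidine (-0.59, log2) and fatty acid (-0.33) lists and away from them in the purine list (-0.20), so a part in some genes stays open. With 2 cultures, which of them stands apart stays open, and no biological explanation was tested.

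The purine, pyrimidine and fatty acid lists changed by the largest amounts among the lists. Gene-specific dye bias is argued against by arrays of both orientations, since the smallest list median among 3 arrays and 3 lists was still 2.39 in size (log2). Signal from other genes on single shared probes would make probes of a list disagree, but the share of the 96 probes with the sign of their list and over 1 in size was 1. Averages of these same probes gave the large changes, so agreement was likely in advance. Probe sequences were not examined, so shared probes stay open. The difference in heme and vitamin K2 between the groups is the explanation that the design names. With 5 cultures in these groups, the cofactors cannot be told apart from each other or from anything else that differed between the groups. Their role as the cause was not tested and stays a hypothesis.

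Across the 10 ways to split the 5 cultures into 3 and 2, 1 gave as many genes past the threshold as the real one, which was the real one with 1092, and the highest of the others gave 0. With 10 splits no share under 0.05 can be reached.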

How the results depend on the processing

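The masked spots and the left-out cultures for reactor 4 were alternatives chosen after seeing the data. For respiring against aerobic cultures, leaving out 1 culture gave 276 to 704 higher and 332 to 744 lower genes. The lowest counts came without reactor 1. Leaving out reactor 5 or 6 gave higher counts than the main fit, but with 1 aerobic culture left the gap between these reactors no longer enters the error. Without reactor 3 there were 285 and 350. The threshold of at least 2-fold gave 128 and 184, by its own construction. All other alternatives run stayed within 1.5 times of 501 and 591, among them the deposited table (568 and 574), no background correction (413 and 456), arrays as replicates (523 and 591) and reactor 4 among the aerobic cultures (409 and 500). Quantile scaling of average intensity leaves log ratios as they are and moved nothing. Single-array omissions kept 82.5% to 96.5% of the 1092 genes. The share of higher genes moved from 45.9% to at most 52.9%, with median centring. For reactor 4, the counts were 6 and 0 without background correction, of which the cause was not tested. Leaving out 1 culture gave 14 to 275 higher and 0 to 191 lower genes. Dropping reactor 5 or 6 (34 and 43) both removes their gap from the error and changes the aerobic mean, which were not separated. The mean spread within a condition was 0.251 and ranged from 0.154 to 0.284. The 4 lists called by camera kept their direction in all 24 alternatives with the preset correlation. Their highest adjusted p there was 0.0017 for purine, 3.9e-05 for pyrimidine, 6.5e-08 for fatty acid and 7.8e-04 for F1F0 ATPase, and fry gave 0.0043 to 0.0084, but all 4 lost the call with an estimated correlation. The median of the uncalled respiratory chain list fell to -0.02 without reactor 6. It was 0.38 over 6 measured members where every channel of a condition had to be above background. Of 924 values of 33 named genes, 893 kept their side of the threshold, 24 lost it and 7 gained it, and no call changed direction. For reactor 4 these were 323, 25 and 12 of 360. Scanner-processed signals and log ratios were not run, since ImaGene files hold none. No paired analysis was run, because the labels describe the cultures as independent and pair none of them across conditions. Signal over background limits array 6 most, with 48.2% of its Cy5 spots above background.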

Other observations

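The test of neighbours in this part was chosen after the result was seen.

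Many genes that changed between respiring and aerobic cultures stood next to each other in locus-tag order, beyond the lists. Counting runs of at least 5 neighbouring measured genes past the threshold in one direction, there were 36 runs with 296 genes, 9 higher and 27 lower in respiring cultures, and 32 held no member of a list. The run with the largest median change outside the lists held 31 genes, from lp_1025 to lp_1062, and was lower in respiring cultures with a median of 8.77-fold. Its members differed by -3.37 to -1.18 on the log2 scale. Among the runs that were higher, the one with the largest median outside the lists held 5 genes, from lp_1359 to lp_1364, with a median of 2.66-fold. The files do not say what these genes are, and both runs were picked after their values were seen.

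There were 549 neighbouring pairs past the threshold in one direction, against a median of 205.5 and a highest value of 239 in 1000 shuffles of the gene order. This count was prompted by the runs and uses the same calls, so it describes them again and decides nothing on why neighbours changed together.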
